A study of Arabidopsis thaliana with 8 samples.

How the data were processed

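Ribosome footprints on mitochondrial mRNAs and RNA editing were measured in flowers of Arabidopsis thaliana plants grown for 10 to 12 weeks, in 8 libraries. Ribosome profiling (Ribo-seq), which sequences the short mRNA fragments that ribosomes protect from nuclease, was made from the wild type Col-0 and from the mutants mtl1 and mtsf1, with 2 libraries (A and B) per genotype. About 2.5 g of flowers was ground and taken up in 15 mL of buffer per the labels' protocols, and libraries were made with a small RNA kit. RNA-seq of total RNA after DNase treatment and removal of ribosomal RNA was made from 2 Col-0 samples. RNA-seq of the mutants was not analysed here, so a footprint change of any gene can reflect mRNA abundance, translation or both. Groups and replicate letters were taken from the sample titles. The labels do not say whether A and B came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

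Reads were handled with FastQC, cutadapt 1.9.1 and Bowtie 1.1.2, and Ribo-seq reads also with featureCounts 1.5.0-p2, per the submitters' processing notes. The genome build, annotation, strand handling, handling of reads that match several places and editing caller are not given in the sources used here. The deposited Ribo-seq table holds 1 normalized score per gene and library, a normalized read count that the authors rounded to whole numbers, for 33 mitochondrial genes. Its normalization method is not given in the sources used here. The median ratio of each library to the gene-wise geometric mean was 1.01 in all 6 libraries, as scaling by median-of-ratios size factors over these genes leaves it. No whole-read step was found in the values, so the reads behind them and the depth of the Ribo-seq libraries are unknown. The totals of the table ranged from 216316 in mtsf1 B to 290301 in Col-0 A, and they are not depths. Per the file headers, the deposited editing tables give for 434 listed sites the count of reads with each base, the reads in all (coverage) and an observed editing fraction, which equals T over T plus C reads within rounding and is left empty by the authors at 10 reads or fewer. The same tables give a reference editing fraction with a spread per site, identical in both files, whose origin is not given in the sources used here. A further file gives the transcript position and sequence around each site.

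Ribo-seq values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, in 1 fit over the 6 libraries with a mean per genotype. Fold changes are on that scale. Genes above 0 in at least 2 libraries were tested, which kept all 33. P-values are two-sided, adjusted by Benjamini-Hochberg over the 33 genes of each contrast, with a threshold of 0.05. limma estimated an infinite prior for the variance, so that all genes shared 1 variance and 99 degrees of freedom stood behind each test in place of 3, and every gene of a contrast has the same standard error. An exact permutation of 2 libraries against 2 cannot give a p below 0.333, so none is reported. Gene lists fixed in advance (complex I, complex III, complex IV, ATP synthase, cytochrome c maturation, ribosomal proteins, and other genes) were tested with camera at a preset correlation of 0.01 where they held at least 3 genes, with Benjamini-Hochberg adjustment over lists and contrasts. fry was run beside it. No list of nuclear or plastid genes had a measured member. The 2 mutants' fold changes were compared without nad4 and nad7, beside 10000 simulated sets of unchanged mutants that shared the Col-0 libraries, and the overlap of their genes beside 1000 such sets. Tested on simulated data for mtl1 against Col-0 over 33 genes, the fit recovered 46.5% of 1.5-fold, 94.2% of 2-fold and 100% of 4-fold changes, and 3.99% of its calls were false. The simulated genes all had the same variance, as the fit assumes. These rates therefore do not test that assumption and hold only where it is met.

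Editing levels were computed as T over T plus C reads. Sites with at least 20 such reads in both RNA-seq libraries were kept (226 of 434 sites, in 24 genes). Wilson 95% confidence intervals and limits cover counting error only. The replicates were compared by Fisher's exact test per site with Benjamini-Hochberg adjustment over the 226 sites. Groups of sites were compared by a two-sided permutation test of mean levels with 100000 resamples, exact where the groups were small enough to enumerate. Sites are not independent replicates. In simulated data at the real read depths, the Fisher test recovered 61.5%, 83.0% and 99.75% of shifts of 10, 20 and 40 percentage points over 226 sites. Each site's sequence was matched to the mitochondrial genome (MT, 367808 bp) of the TAIR10.1 assembly, whose build may not be the one the authors used. Of the 434 sequences, 429 matched without a mismatch and 5 with 1. Positions are given on that assembly, counted from 1. Codons and amino acids were read from its annotation with the other bases of the codon as in the genome. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

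The tests of the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined, except the settings without moderation of the variance, without the nad5 site with T in the genome and with other sites of a codon edited. The tests of explanations were also chosen later, those of the preceding base and of footprint level before their own results were seen and the others after. The rule named nad7 and nad4, up to 20 genes past the threshold in each contrast, and in each list the gene not past the threshold with the largest and the one with the smallest change. For Col-0 it named the 5 highest and 5 lowest genes. For editing it named the 5 lowest and 5 highest coding sites, up to 5 sites that differed between replicates, the 5 genes with the most sites, and the 3 genes with the lowest and the 3 with the highest mean level among genes with at least 5 sites. Alternatives covered pseudocounts of 0.1 and 10, other scalings, filters, variance settings, a fit of the compared genotypes alone, a replicate term, coverage minimums of 1, 50 and 100 reads, and leaving out each library. Editing of the Ribo-seq libraries was not analysed here. The atp6-1 and atp6-2 genes share most of their sequence (732 words of 30 bases, 64.8% and 71.7% of the words of the 2 annotated copies), and rps3 and rpl16 overlap by 134 bases, so counting could have split or shared their reads and their values are uncertain.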

Results

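Ribosome occupancy of mitochondrial mRNAs was compared between flowers of wild type Arabidopsis (Col-0) and of the mutants mtl1 and mtsf1, and the editing of mitochondrial transcripts was measured in Col-0. MTL1 (mitochondrial translation factor 1) and MTSF1 (mitochondrial stability factor 1) are pentatricopeptide repeat proteins, a family of organellar RNA-binding proteins, needed for translation of the nad7 mRNA and for stability of the nad4 mRNA respectively. The data were 6 Ribo-seq libraries, 2 per genotype, with normalized footprint counts for 33 mitochondrial genes, and 2 Col-0 RNA-seq libraries with base counts at listed editing sites, of which 226 had enough reads and 208 did not. Replicate libraries correlated across the 33 genes with r = 0.993 in Col-0, 0.990 in mtl1 and 0.988 in mtsf1 on the log2 scale. The median difference between replicates was 0.31, 0.20 and 0.27 log2 units. At the editing sites the RNA-seq libraries held 46892 reads (A, median 24 per site) and 100704 reads (B, median 43).

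The targeted genes were examined first. nad7 encodes a subunit of the matrix arm of complex I (NADH dehydrogenase) and lies in 5 coding segments on the minus strand between MT 239250 and 245330. Its footprints numbered 8132 and 6785 normalized counts in Col-0, 460 and 394 in mtl1, and 7839 and 6273 in mtsf1. nad4 encodes a membrane arm subunit of complex I and lies in 4 coding segments on the minus strand between MT 207580 and 215562. Its footprints numbered 13818 and 11147 in Col-0, 10044 and 10721 in mtl1, and 216 and 207 in mtsf1. nad7 was 17.4-fold lower in mtl1 than in Col-0 (95% interval 12.6 to 24.0; n = 2 libraries each) and nad4 was 58.4-fold lower in mtsf1 (95% interval 42.4 to 80.6). The limma adjusted p (Benjamini-Hochberg) was 8.5e-31 for nad7 in mtl1 and 3.3e-43 for nad4 in mtsf1. With each gene's own variance, a setting chosen after seeing the data, limma gave adjusted p values of 0.0073 and 0.00088.

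**Figure D1:**
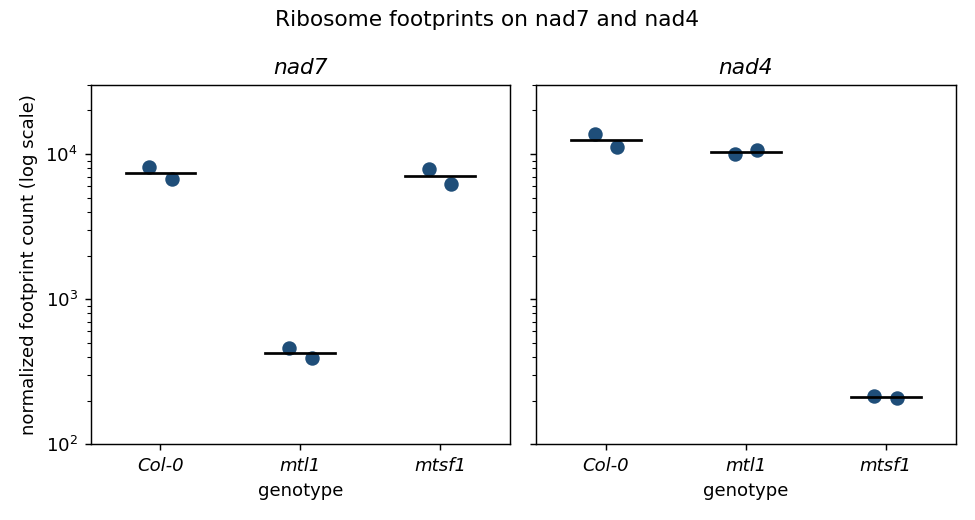
Normalized footprint counts of nad7 and nad4 (log axis) in the 2 libraries of each genotype, with points for libraries and bars for means. The nad7 points of mtl1 (460 and 394) lie below those of the other genotypes, and the nad4 points of mtsf1 (216 and 207) lie below those of the other genotypes.

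Footprints in wild type mitochondria fell mainly on genes of the respiratory chain and ATP synthase. The 6 ATP synthase genes held 35.6% ± 1.86 (SD, n = 2) of the Col-0 total, the 3 complex IV genes 27.8% ± 2.19, the 9 complex I genes 26.9% ± 0.186, and cob of complex III 6.06% ± 0.273. The 7 ribosomal protein genes held 1.99% ± 0.134, the 5 cytochrome c maturation genes 1.18% ± 0.157, and matR and mttB together 0.356% ± 0.0410. The 5 highest genes were atp1 (39412 ± 1180 normalized counts), cox2 (27579 ± 924), cox1 (25507 ± 1824), cox3 (24800 ± 4950) and atp9 (18697 ± 6815), which held 48.5% ± 0.389 of the total. The 5 lowest were rpl2 (507 ± 180), ccmC (493 ± 76.4), matR (346.5 ± 75.7), rpl16 (338.5 ± 61.5) and ccmB (293.5 ± 24.7). These values were not divided by gene length. Per kilobase of coding length, without the atp6 genes, atp9 was highest (83098 ± 30289) and matR lowest (176 ± 38.4).

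Beyond nad7, footprints of 10 genes differed between mtl1 and Col-0. In complex I, nad9 also fell, with a log2 fold change of -1.16, and 7 of the 9 genes did not pass the test, nad4 (-0.26), nad6 (-0.48) and nad4L (-0.13) among them. In the ATP synthase, atp6-1 (-1.20), atp6-2 (-0.78) and atp9 (-0.57), which encode membrane subunits of the proton channel, fell, while 3 of 6 genes did not pass, with atp8 at -0.40 and atp4 at -0.16. The value of atp6-1 ranged from -1.60 to -0.79 with 1 library left out. cob, the apocytochrome b of complex III, rose (0.66). In cytochrome c maturation, which attaches heme to c-type cytochromes, ccmC (0.82) and ccmFN1 (0.68) rose and 3 of 5 genes did not pass, with ccmFN2 at -0.33 and ccmB at 0.27. Of the 7 ribosomal protein genes, rps12 (1.09) and rpl5 (0.86) rose, rpl16 (-0.85) fell and 4 did not pass, with rps4 at 0.49 and rps7 at 0.26. No complex IV gene passed, with cox3 at -0.45 and cox1 at -0.02, which lay at 0.07 after scaling to equal totals. Nor did mttB (-0.55), a membrane transport protein gene, or matR (-0.52), an intron maturase gene. mttB rested on mtl1 A, with -0.072 without that library and -1.02, past the threshold, without mtl1 B, matR passed without Col-0 B (-0.74), and nad6 without mtl1 B (-0.77, and -0.19 without mtl1 A).

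The limma test called 11 of 33 genes in mtl1 at an adjusted p below 0.05 (Benjamini-Hochberg), 5 higher and 6 lower, with a standard error of 0.23 log2 units for every gene. Adjusted over the list alone, the counts were the same in complexes I, III and IV, ATP synthase, cytochrome c maturation and ribosomal proteins, and both genes of the other list passed. The adjusted p of the genes called ranged from 8.5e-31 for nad7 to 0.0486 for atp9. After scaling to equal totals 11 genes again passed, 6 higher and 5 lower, with atp9 lost and rps4 added. When each of the 6 libraries was left out in turn, nad7, nad9, atp6-1 and rps12 passed every time, while without Col-0 B 1 gene was higher and 7 lower, and without mtl1 B 2 were higher and 6 lower. ccmC, ccmFN1 and cob were lost in both of these cases and rpl5 without Col-0 B, while atp6-2 was lost without Col-0 A, rpl16 without Col-0 A or mtl1 B, and atp9 (-0.19 at its smallest) without any library but Col-0 B. With a variance that follows the level of the gene, 9 genes passed, 6 higher and 3 lower: atp6-2, atp9 and rpl16 were lost and atp1 (0.38) was added. With each gene's own variance, chosen after seeing the data, only nad7 passed.

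In mtsf1, footprints of ribosomal protein genes and of matR were higher than in Col-0. Of 7 ribosomal protein genes, 6 rose: rpl16 (log2 fold change 1.43), rpl5 (1.20), rpl2 (1.07), rps12 (1.0), rps3 (0.99) and rps7 (0.64), while rps4 (0.21) did not pass. matR rose most (1.88; 346.5 ± 75.7 normalized counts in Col-0 and 1268 ± 54.4 in mtsf1, SD, n = 2). In cytochrome c maturation, ccmC (0.97) and ccmFN1 (0.75) rose and 3 of 5 genes did not pass, with ccmFC at 0.49 and ccmFN2 at 0.25. In complex I, nad2 (-1.62) and nad9 (-0.98) fell along with nad4, and 6 of 9 genes did not pass, nad7 (-0.08), nad1 (-0.26) and nad3 (0.02) among them. After scaling to equal totals nad7 lay at 0.25 and nad1 at 0.07. In the ATP synthase, atp8 (-1.17), atp9 (-1.12), atp6-1 (-0.98) and atp6-2 (-0.96) fell, and atp4 (-0.46) and atp1 (0.03) did not pass. With 1 library left out atp9 ranged from -1.50 to -0.74 and the ribosomal protein gene rpl2 from 0.70 to 1.44. cob (0.24), cox2 (-0.37), cox3 (-0.16, and 0.18 after scaling to equal totals) and mttB (-0.51) did not pass.

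The limma test called 16 of 33 genes in mtsf1 at an adjusted p below 0.05 (Benjamini-Hochberg), 9 higher and 7 lower, with a standard error of 0.23 log2 units. Adjusted p ranged from 3.3e-43 for nad4 to 0.0154 for rps7. Adjusted over the list alone, the counts were the same in every list but the other genes, where mttB also passed. The deposited mtsf1 totals were lower than those of Col-0, so scaling to equal totals raised the median over all genes from 0.03 to 0.36, and 21 genes then passed, 14 higher and 7 lower, with all 16 among them. The mean of the complex IV list then turned from -0.26 to 0.075. Without Col-0 B or without mtsf1 A, rps7 no longer passed (0.48 without mtsf1 A), and the other 15 genes passed with any library left out. With each gene's own variance, chosen after seeing the data, 4 genes passed: nad4, nad2, matR and ccmFN1.

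**Figure D2:**
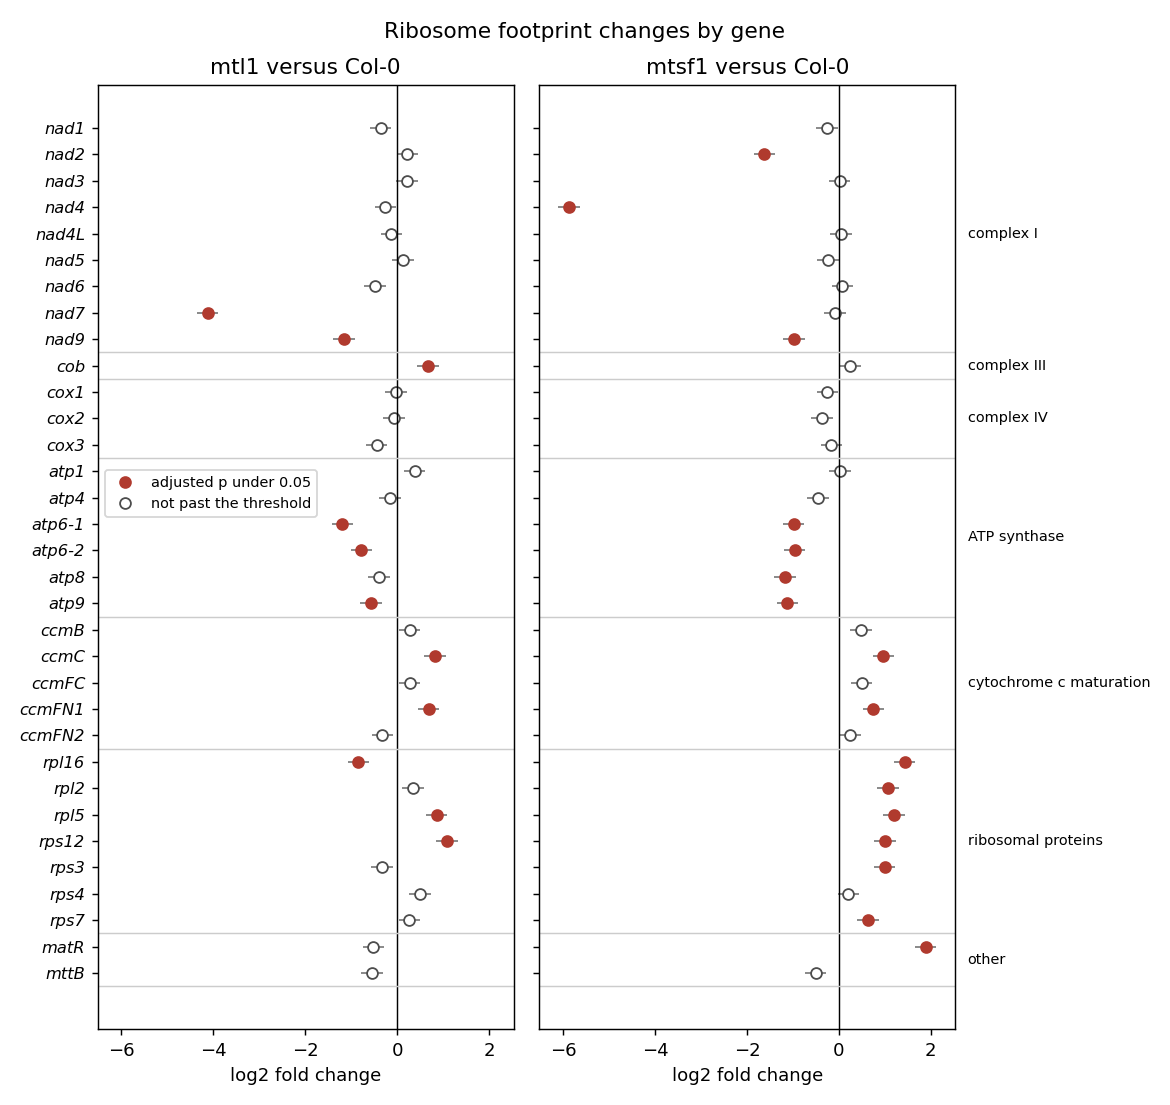
Log2 fold changes of 33 genes in mtl1 and mtsf1 against Col-0 (horizontal axis), grouped by gene list, with standard errors as bars and filled points for genes at an adjusted p below 0.05 by limma. nad7 lies at -4.12 in mtl1 and nad4 at -5.87 in mtsf1, and 6 of 7 ribosomal protein genes are filled to the right of 0 in mtsf1.

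As whole lists, none of the 5 lists with at least 3 genes stood apart from the other genes by camera at an adjusted p below 0.05 in any contrast. At an unadjusted p below 0.05, limma camera gave 3 results, all in mtsf1: ribosomal proteins (median log2 fold change 1.0, adjusted p = 0.0558), complex I (median -0.24, adjusted p = 0.128) and ATP synthase (median -0.97, adjusted p = 0.231). The ribosomal protein list lay close to the threshold. Its limma camera adjusted p was 0.0251 without Col-0 A, 0.0372 without Col-0 B, 0.0421 without either mtl1 library, 0.0480 without mtsf1 B and 0.0851 without mtsf1 A, and 0.610 with an estimated correlation. The complex I result by camera rested on the targeted genes: without nad4 and nad7 the mean went from -0.99 to -0.42 in mtsf1 (limma adjusted p = 0.471) and from -0.66 to -0.22 in mtl1 (0.827). The median of complex I in mtsf1 turned to 0.097 after scaling to equal totals, while its mean stayed below 0.

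By limma fry, which asks whether the genes of a list moved 1 way on balance, complex I passed in mtl1 (adjusted p = 0.0029) and mtsf1 (0.0017). Both calls held without nad4 and nad7 (limma fry adjusted p = 0.0032 and 0.0010), a list not run after scaling to equal totals. The mean of the whole complex I list stayed at -0.69 to -0.63 in mtl1 and -1.02 to -0.96 in mtsf1 with each library left out in turn. Of the genes other than nad4 and nad7, only nad9 was called in mtl1. There nad1, nad4L and nad6 lay below 0, and nad2 (0.22), nad3 (0.21) and nad5 (0.13) above. In mtsf1 nad2 and nad9 were called. There nad1 and nad5 lay below 0, and nad3 (0.02), nad4L (0.05) and nad6 (0.08) above. ATP synthase in mtsf1 passed by limma fry (adjusted p = 0.0226), but with 1 library left out only the fit without Col-0 B passed (0.0304), and the others gave 0.0503 without Col-0 A, 0.0958 and 0.0860 without mtl1 A and B, and 0.111 without either mtsf1 library. Ribosomal proteins in mtsf1 passed with all libraries (limma fry adjusted p = 0.0376) and in none of the fits without a library: 0.0595 without Col-0 A, 0.0803 without Col-0 B, 0.123 without either mtl1 library, 0.126 without mtsf1 A and 0.111 without mtsf1 B. Complex I in mtl1 against mtsf1 had a limma fry adjusted p = 0.0152, upward, with a mean of 0.33 and a median of -0.10. It no longer passed after scaling to equal totals (0.103), or without mtl1 A (0.0958), mtl1 B (0.0860), mtsf1 A (0.0652) or mtsf1 B (0.111). Cytochrome c maturation in mtsf1 did not pass as deposited (limma fry adjusted p = 0.0869) and passed after scaling to equal totals (0.0196). The same scaling moved the limma fry adjusted p of ATP synthase in mtl1 from 0.0661 to 0.0489 and that of ribosomal proteins in mtl1 against mtsf1 from 0.0661 to 0.0196. Complex IV passed by neither test, and its medians were -0.07 in mtl1 and -0.25 in mtsf1, which turned to 0.022 and 0.084 after scaling to equal totals.

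Compared with each other, the mutants differed most in their targeted genes. nad4 was higher in mtl1 than in mtsf1 (log2 fold change 5.61) and nad7 was lower (-4.04). nad2 (1.84) and atp8 (0.77) were higher in mtl1, and matR (-2.40), rpl16 (-2.28), rps3 (-1.33) and rpl2 (-0.73) were lower. Genes not past the threshold included atp9 (0.55), nad6 (-0.55), cob (0.42), cox2 (0.30), ccmFN2 (-0.58), ccmFN1 (-0.07), nad1 (-0.10), mttB (-0.04), rps7 (-0.38), and, with signs that turned after scaling to equal totals, cox1 (0.23), atp6-2 (0.18) and rps12 (0.09). limma called 8 of 33 genes (adjusted p below 0.05, Benjamini-Hochberg), 3 higher and 5 lower, and adjusted over the list alone the count rose in complex I, where nad6 also passed. Scaled to equal totals the median over all genes moved from -0.10 to -0.34 and 13 genes passed, 3 higher and 10 lower. With mtl1 A or mtsf1 A left out, 6 genes passed and atp8 and rpl2 no longer did.

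Genes that moved in both mutants against Col-0 were ccmC, ccmFN1, rpl5 and rps12, which rose in both, and nad9, atp6-1, atp6-2 and atp9, which fell in both. rpl16 fell in mtl1 and rose in mtsf1. Single libraries decided most of these genes: without Col-0 B 1 gene was higher and 4 lower in both, without Col-0 A 5 were higher and 2 lower, and without mtl1 B 2 were higher and 3 lower. rps12, nad9 and atp6-1 were shared with any library left out. With all libraries, the 4 and 4 genes compare with 1.36 and 1.27 for independent lists of the same lengths, and with 0.005 and 0.009 in simulated unchanged mutants that shared the Col-0 libraries. Unchanged mutants give almost no calls and independent lists leave out the shared controls, so neither number is the overlap to expect of 2 changed mutants. Across the 31 genes other than nad4 and nad7, which are not independent replicates, the fold changes of the 2 mutants had r = 0.428 and rho = 0.479, against means of 0.494 and 0.460 in the simulated mutants. Their covariance was 0.211, against a simulated mean of 0.0285. Fold changes of the simulated mutants hold only noise, part of it shared through Col-0. The simulated r and rho are therefore not those to expect of 2 changed mutants. Both comparisons used the same 2 control libraries, and part of the overlap may come from them.

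Editing converts cytidines of plant mitochondrial transcripts to uridines, read as C-to-T changes in RNA-seq, and its rate in Col-0 was the stated purpose of the RNA-seq. Editing was near complete at most sites. Over the 226 sites with at least 20 reads in both libraries, the mean level was 89.0% ± 0.0758 (SD of library means, n = 2) and the median 99.9%. Of these sites 195 were edited at 90% or more, 15 between 10% and 90%, and 16 below 10%. Without library A, where 276 sites had at least 20 reads in B, the middle class held 25 sites. With bounds of 5% and 95% over the 226 sites it held 28 and the lowest class 6. The highest coding sites were cox2 position 680 (0 unedited of 1439 reads in A and of 3063 in B), atp1 1538, nad3 482, nad4 334 and nad5 784, numbered by transcript position, all at 100% in both libraries. They change Ser to Leu (cox2 codon 159 at MT 6739, atp1 codon 393 at MT 67444, nad5 codon 238 at MT 235895) or Pro to Leu (nad3 codon 84 at MT 288294, nad4 codon 36 at MT 215456).

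The lowest coding sites were all synonymous. ccmB 580 (MT 17994) had 0 edited reads of 20 in A and of 26 in B, with Wilson 95% upper limits of 16.1% and 12.9%. nad4 645 (MT 215145) was edited at 0.331% ± 0.468 (SD, n = 2 libraries), nad5 2000 (MT 28255) at 0.461% ± 0.174, nad2 406 (MT 163064) at 1.28% ± 0.675 and rps3 288 (MT 21873) at 1.75% ± 1.34. The deep coverage of nad5 2000 gave narrow Wilson intervals, 0.296% to 1.15% of 1369 reads in A and 0.202% to 0.567% of 4140 reads in B. These intervals cover counting error only and not errors of base calling. Reads with A or G at this site numbered 0 in A and 4 of 4144 in B (0.0965%).

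The 2 RNA-seq libraries gave nearly equal levels at most sites (r = 0.995 and rho = 0.656 across 226 sites). The absolute difference had a median of 0.0522 percentage points and a largest value of 16.4. With 144 sites in A and 128 in B at 100%, neither r nor the median shows how closely sites at intermediate levels agreed. By Fisher's exact test with Benjamini-Hochberg adjustment 1 site differed, and 4 had an unadjusted p below 0.05. This site lies in the nad7 transcript 39 bases before the start of the coding sequence (MT 245369, minus strand). It was edited at 46.1% of 958 reads in A (Wilson 95% interval 43.0 to 49.3) and 57.1% of 883 reads in B (53.8 to 60.3), with an adjusted p of 0.00068 by Fisher's exact test. The test compares these libraries and not conditions, and it treats each read as independent, so its p covers counting error only.

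Synonymous sites, whose editing leaves the amino acid as it is, were edited far less than nonsynonymous ones. The 35 synonymous sites averaged 40.7% and the 187 nonsynonymous sites 98.4%, a difference of -57.7 percentage points (-57.2 in A and -58.2 in B). The permutation test gave p = 2.0e-05, the smallest that its 100000 resamples can give. With gene means as units, the difference was -50.3 points in 12 genes that held both classes (exact sign-flip permutation p = 0.00049). The synonymous mean depended on the coverage minimum, at 27.1% over 22 sites with at least 50 reads (difference -72.4 points) and 18.3% over 11 sites with at least 100 (difference -81.3). Levels within the synonymous class spread from 0% at ccmB 580 to 100% at nad4 351 and cox2 231, and the sites named here were chosen after their values were seen. The nonsynonymous sites below 50% were ccmFN1 632 (Arg to Cys, 5.66% ± 4.07, SD, n = 2 libraries) and rpl5 579 (Pro to Ser, 9.27% ± 7.09).

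**Figure D3:**
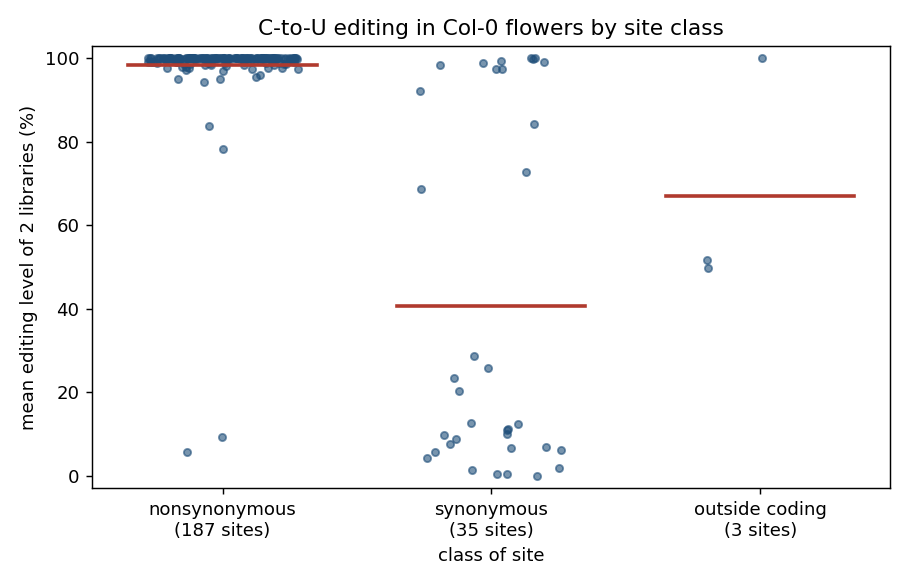
Mean editing level of the 2 Col-0 RNA-seq libraries (vertical axis, percent) at each kept site, by class of site, with red bars for class means. Nonsynonymous sites (mean 98.4%) lie near 100% and synonymous sites (mean 40.7%) spread over the whole range. The 1 kept coding site with T in the reference genome has no class and is left out.

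By codon position, the 32 sites at position 3 averaged 41.2% ± 0.603 (SD of library means, n = 2), the 124 at position 2 99.5% ± 0.220 and the 67 at position 1 93.4% ± 0.0352. The difference of position 3 from the others was -56.2 points, and the permutation test gave p = 2.0e-05, the smallest it can give. A C-to-T change at position 3 leaves the amino acid as it is. This comparison therefore largely repeats the synonymous one on the same sites and is not separate evidence. Without the nad5 site with T in the genome, position 3 averaged 39.3% over 31 sites (difference -58.1 points). The gene-wise difference was -52.4 points in 11 genes (exact sign-flip permutation p = 0.00098). The mean at position 3 was 25.8% over 19 sites with at least 50 reads (difference -72.3 points) and 10.6% over 9 sites with at least 100 (difference -87.8). Sites in coding sequence averaged 89.3% (223 sites) and the 3 sites outside it 67.1%, with an exact permutation p = 0.19. No difference was detected, and what 3 sites could detect was not tested. The difference of 22.2 points was 6.27 with all sites read in both libraries (7 noncoding sites) and 38.5 with at least 50 reads (2 noncoding sites).

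Mean editing was compared between genes by their kept sites. Among the 15 genes with at least 5 kept sites, cob (77.4% ± 0.935, 8 sites), nad2 (81.4% ± 0.00014, 20 sites) and atp1 (81.7% ± 0.230, 5 sites) were lowest, and nad9 (99.9% ± 0.0944, 7 sites), nad3 (99.65% ± 0.409, 11 sites) and nad1 (99.5% ± 0.118, 15 sites) were highest (SD of library means, n = 2). The low means came from a few synonymous sites: 2 of 8 in cob (6.68% and 12.5%), 4 of 20 in nad2 (1.28% to 25.8%) and 1 of 5 in atp1 (8.87%), while the nonsynonymous sites of these genes lay at 95.04% or more. The genes with the most listed sites were nad4 (38 listed, 84.7% over 31 kept), nad5 (33 listed, 87.2% over 30), nad2 (31 listed), nad7 (31 listed, 89.2% over 25) and ccmB (26 listed, 3 kept). By list, complex IV averaged 97.0% ± 0.396 (21 sites), complex I 90.1% ± 0.158 (154 sites), ATP synthase 88.3% ± 0.0453 (17 sites), ribosomal proteins 81.7% ± 1.30 (17 sites), complex III 77.4% ± 0.935 (8 sites) and cytochrome c maturation 77.3% ± 1.64 (9 of 98 listed sites). Low coverage left 208 sites out: 17 of 58 listed sites were kept in ribosomal protein genes and 0 of 34 in matR and mttB.

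The measured levels were also set beside the reference levels in the deposited tables, whose origin is not given in the sources used here. Across the 226 sites they had r = 0.960 and rho = 0.536. The measured level lay above the reference by a mean of 2.11 points and a median of 0.81 points. At 9 sites the measured level was over 20 points above the reference and at 1 it was over 20 points below. The 9 sites were in nad3 (3), rpl5 (3), rps4 (2) and ccmC (1), and the 1 was nad5 872, at 23.4% against 47% in the reference. These sites were chosen after their values were seen.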

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

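The tests of explanations for the 3 patterns in this part were chosen after the results were seen. The genes named first are those whose footprints differed between the mutants, mtl1 against mtsf1, at an adjusted p below 0.05 by limma. Their log2 fold changes were -4.04 for nad7, -2.40 for matR, -2.28 for rpl16, -1.33 for rps3, -0.73 for rpl2, 0.77 for atp8, 1.84 for nad2 and 5.61 for nad4. The mutated proteins act on nad7 and nad4. The difference for nad2 came from mtsf1, where nad2 fell by 1.62 log2 units against Col-0, while it lay at 0.22 in mtl1.

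The ribosomal protein genes were higher in mtsf1, with 6 of 7 past the threshold, although the list as a whole did not pass camera (limma, adjusted p = 0.0558). A single scaling factor per library moves all genes alike and cannot change the gap between this list and the other genes. The list's median exceeded that of the other genes by at least 0.88 log2 units in all 4 pairs of mtsf1 and Col-0 libraries. This gap gives only the list's position relative to the other genes. It cannot tell whether the list rose or the other genes fell. A uniform background of reads would add the same count per kilobase to every gene and to nad4, which kept 139 to 145 normalized counts per kilobase in mtsf1. The median gain of the list was at least 366 per kilobase in each pair of libraries, above that bound. This measure was taken up after the smallest gain between group means, 224 for rps4, had been seen. A median does not speak for each gene: rps4 stood at 1666 in Col-0 B and 1771 in mtsf1 B over 1089 coding bases. Single genes were not set against the bound in each pair of libraries. A change in the abundance of these mRNAs was not tested, because RNA-seq of the mutants was not analysed here, and rps3 and rpl16 share 134 bases, so they are not separate evidence.

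The fold changes of mtl1 and mtsf1 went together, with 4 genes higher and 4 lower in both, of which rps12, nad9 and atp6-1 were shared with any library left out (1 higher without Col-0 B, 2 lower without Col-0 A, 2 higher without mtl1 B). Noise that differs between the shared Col-0 libraries gives 10.6% of the covariance (9.21% to 12.5% with 1 mutant library left out), and so not all of it. A deviation common to both Col-0 libraries would enter both comparisons, is not in that share, and stays open. The correlation itself (r = 0.428) was below the mean of simulated unchanged mutants (0.494). Fold changes of those simulated mutants hold only noise, so this does not tell whether mtl1 and mtsf1 responded alike. A response shared by both complex I mutants was not tested, since no mutant outside complex I was analysed here.

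The nad5 site at transcript position 1346 (coding base 1275, MT 236457, plus strand) is listed at 100% editing, with 36 reads in A and 74 in B. The reference genome has T at this position and 0 of 110 reads had C, which allows a share of up to 2.73%, while the other 433 sites have C in the genome. T in the genome may account for the value, and genomic DNA was not analysed here. Without this site the mean editing level was 89.0%.

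At editing sites, reads with A or G, which no editing comparison used, exceeded the 3 reads that a count of 0 allows at 5 sites, with no control samples to set them against. In A these were cox2 583 (7 reads of 2811, 0.249%), cox2 680 (4 of 1443), cox2 761 (4 of 5505) and nad4 1204 (8 of 274, 2.92%). In B they were cox2 583 (6 of 7836), cox2 761 (8 of 9246) and nad5 2000 (4 of 4144). The nad4 site at 1204 is the first base of the 3rd coding segment of nad4 (MT 210033).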

How the results depend on the processing

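The settings without a shared variance, without the nad5 site at 1346 and with other sites of a codon edited were chosen after seeing the data. nad7 in mtl1 and nad4 in mtsf1 kept their direction and passed under every setting run (log2 fold changes -3.99 to -4.25 and -5.53 to -6.02). Median-of-ratios scaling and no filter moved no call, since the deposited values already had equal median ratios and no gene was at 0. With each gene's own variance, 1 gene passed in mtl1, 4 in mtsf1 and 6 between the mutants. Between mutants, scaling to equal totals gave 13 genes. With 1 library left out 8 to 10, 15 to 17 and 6 to 10 genes passed in mtl1, mtsf1 and between the mutants, the lone library being assumed to vary like the others. The letters A and B only share a letter (correlations of same-letter deviations 0.066, 0.0039 and -0.14), and with a replicate block 10, 16 and 8 genes passed, atp9 in mtl1 being the gene lost, and 1 gene list passed camera, ribosomal proteins in mtsf1 (adjusted p 0.0415, but 0.610 with an estimated correlation). By fry under the block ATP synthase in mtsf1 no longer passed (0.0724) and ribosomal proteins between the mutants did (0.0237). Without 1 library 0 to 1 lists passed, and the list was again ribosomal proteins in mtsf1 (adjusted p 0.0251 to 0.0851 over those settings, 0.0732 after scaling to equal totals). r between the mutants was 0.374 to 0.512 with 1 library left out and 0.195 with all 33 genes.

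Genes not past the threshold changed sign. Scaling to equal totals shifts all genes of a contrast by nearly the same amount, so values near 0 cross it. Scaled to equal totals, and likewise without nad4 and nad7, the values were 0.070 and 0.025 for cox1 in mtl1, 0.25 and 0.19 for nad7, 0.074 and 0.016 for nad1 and 0.18 and 0.12 for cox3 in mtsf1, and between the mutants -0.060 and -0.047 for atp6-2, -0.014 and -0.00081 for cox1, and -0.16 and -0.14 for rps12. The complex IV mean was then -0.16 between the mutants and 0.075 in mtsf1. With 1 library left out, where the cause was not tested, the ranges were -0.27 to 0.015 for nad4L and -0.096 to 0.050 for cox1 in mtl1, -0.24 to 0.038 for nad1, -0.51 to 0.44 for mttB, -0.16 to 0.34 for rps12 and -0.019 to 0.17 for the complex IV mean between the mutants, and -0.24 to 0.078 for nad7, -0.097 to 0.15 for atp1, -0.27 to 0.30 for nad3 and -0.37 to 0.045 for cox3 in mtsf1.

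Per kilobase, without atp6, the Col-0 shares were 45.1% ATP synthase, 23.8% complex I, 4.06% complex III, 23.4% complex IV, 1.02% cytochrome c maturation, 0.270% other and 2.25% ribosomal proteins. Mean editing was 85.8% at a coverage minimum of 1, 88.6% at 50, 88.7% over pooled reads and 88.0% to 88.6% in single libraries. Single-library values here and below use all sites with at least 20 reads in that library (235 in A and 276 in B). Over the 226 sites kept in both, the means were 88.96% in A and 89.06% in B. Sites at 90% or more, between and below 10% numbered 313, 54 and 29 at a minimum of 1 and 77, 5 and 7 at 100. The middle class held 16 to 25 sites in single libraries, 9 with bounds of 20% and 80%, and 28 with bounds of 5% and 95%, which left 6 below. The lowest gene mean was 49.9% (rps3) at a minimum of 1, 71.7% (nad2) at 50, and 66.6% to 78.0% in single libraries. The synonymous and codon position differences kept their direction and passed under every setting run, with differences of -50.3 to -81.3 and -52.4 to -87.8 points, and the noncoding comparison, with too few sites at 100, passed under none. edgeR with TMM factors, planned for raw counts, and editing in footprints were not run. The unknown depth of the Ribo-seq libraries limits the lowest genes.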

Other observations

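The neighbouring genes, the test of read depth and the check of nonsynonymous sites alone were chosen only after the results were seen, while the tests of the preceding base and of footprint level were set before their own results were seen. For 7 chosen pairs of neighbouring genes the log2 fold changes are given as values, and no relation to gene order was tested. The pairs follow no distance rule and are not all the close ones. rps4 and nad2, for example, lie closer together than cob and rpl5 and are left out. rps3 and rpl16 (MT 20165 to 23824, plus strand) overlap by 134 bases, and nad9 lies 840 bases after rpl16. In mtsf1 rps3 and rpl16 rose (0.99 and 1.43) and nad9 fell (-0.98), while in mtl1 rpl16 and nad9 fell (-0.85 and -1.16) and rps3 (-0.33) did not pass. cob and rpl5 are 1903 bases apart, and both rose in mtl1 (0.66 and 0.86), while in mtsf1 rpl5 rose (1.20) and cob (0.24) did not pass. nad3 and rps12 are 45 bases apart, and rps12 rose in mtl1 (1.09) and mtsf1 (1.0) while nad3 did not pass (0.21 and 0.02). matR lies between coding segments 4 and 5 of nad1, inside an intron of nad1, and rose in mtsf1 (1.88) while nad1 did not pass (-0.26). In mtl1 neither passed (-0.52 and -0.36). mttB and rpl2 are 163 bases apart, and rpl2 rose in mtsf1 (1.07) while mttB did not pass (-0.51), nor did either in mtl1 (0.34 and -0.55). nad4L and atp4 are 266 bases apart and did not pass in mtl1 (-0.13 and -0.16) or mtsf1 (0.046 and -0.46).

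Among the listed editing sites, T stands directly before the site at 272, C at 131, A at 20 and G at 11. The most common amino acid changes were Ser to Leu (90 sites), Pro to Leu (77), Ser to Phe (43) and Pro to Ser (40). The change Arg to stop occurred in ccmFC at codon 443 (100% edited, 10 reads in A and 12 in B, under the coverage minimum). Codon 443 is the last codon of the annotated coding sequence of 1329 bases. Gln to stop occurred in rpl16 at codon 21, within the 134 bases shared with rps3, and no reads were found there.

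Sites after a purine may be edited less completely: 11 of 15 coding sites after A or G (73.3%) and 182 of 207 after C or T (87.9%) reached 90%, and Fisher's exact test gave p = 0.115, adjusted p = 0.173 over 3 tests (Benjamini-Hochberg). Among nonsynonymous sites alone the shares were 83.3% of 12 and 98.9% of 175 (Fisher's exact p = 0.0212, unadjusted, outside the 3 tests and not predicted), so the question stays open. Across 15 genes, which are not independent replicates, mean editing and Col-0 footprints per kilobase had rho = 0.229 (permutation p = 0.409, adjusted p = 0.409) and r = 0.197 (permutation p = 0.481). No relation was detected across these 15 genes. Synonymous sites with more reads may be edited less: across 35 sites level and log10 reads had rho = -0.271 (permutation p = 0.115, adjusted p = 0.173) and r = -0.321 (permutation p = 0.059), which did not pass.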
